A study of Mus musculus with 3 samples.

How the data were processed

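ChIP-seq was carried out on beige adipocytes differentiated from stromal-vascular cells of inguinal white fat of C57BL/6 mice. Per the labels' protocols, cells were grown in medium with 20% fetal bovine serum for 3 days and on to confluence. They were then induced for 48 h in medium with 10% serum, 5 µg/ml insulin, 0.5 mM isobutylmethylxanthine, 1 µM dexamethasone, 50 nM T3 and 5 µM troglitazone, and kept afterwards with insulin, T3 and troglitazone. Per the labels' protocols, nuclei were sonicated and DNA was recovered with an antibody against Foxp4. The labels give this text for all 3 libraries and name no antibody for H3K27ac. The libraries comprise input DNA, Foxp4 ChIP and H3K27ac ChIP, 1 of each, assigned by sample title. The input library was not used here.

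Bowtie2, Picard, SAMtools, MACS2 and deepTools 3.3.0 and the mm10 build are named in the submitters' processing notes, without their settings. Per the file headers, each deposited file is a narrowPeak list of 1 library annotated with HOMER annotatePeaks.pl on mm10, with the nearest RefSeq TSS, the signed distance from the peak centre to it, the annotation class and the repeat or CpG island at the peak. The deposited score of each peak is a whole number of at least 20. MACS2 by default writes a multiple of the −log10 q-value in that column, which the files do not state, and no fold enrichment column was there. How the input was used in peak calling and the threshold of the call are not given in the sources used here. Read numbers cannot be seen in the lists, so depth is unknown, and a shallower library would yield fewer and lower-scoring peaks. For this reason scores were compared only within a list.

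Peaks on chromosomes 1 to 19, X and Y were used, which left out 1 Foxp4 peak on the mitochondrial genome. No peaks of a list overlapped one another. A promoter peak was a peak whose centre lay within 1000 bp of the TSS in the deposited distance column. Overlap meant at least 1 shared bp. It was compared with 1000 circular rotations of the peaks along each chromosome, between the first and the last position that either list covers. The p is two-sided, and shares have exact Clopper-Pearson 95% intervals. Median scores were compared by a two-sided permutation test with 100000 resamples, and shares of peaks or genes by two-sided Fisher's exact tests. The interval of the odds ratio is a normal approximation on the log scale. Rotation keeps the spacing of peaks but places them in unmappable sequence as well, so the rotated share is a low estimate of chance among mappable or open chromatin.

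Genes were taken from the deposited annotation through Entrez identifiers. The background was 21031 protein-coding genes of the RefSeq annotation of GRCm38.p6, the assembly of mm10. The 25 gene lists were written before the data were examined and hold 610 entries matched to that annotation, and 1 symbol did not match. Lists were tested against the remaining genes of the same background, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The main test of Foxp4 used genes with an H3K27ac promoter peak as background.

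Genes named in the text followed a rule written beforehand. It covered 20 fixed genes, the 10 highest-scoring Foxp4 promoter peaks overlapping H3K27ac and the 5 highest without overlap, the 5 strongest Foxp4 peaks, the 5 genes with the most Foxp4 peaks (6 where tied), and the list members with the highest-scoring Foxp4 promoter peaks. Predicted gene models and microRNAs were passed over. Genes named for a number of assigned peaks, and members of lists named for an H3K27ac promoter peak were chosen after their values were seen.

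The design had foreseen fold enrichment as the strength of a peak, with the score in its absence, and the score was used. A planned search for the forkhead motif needs the genome sequence and was not run. Alternatives covered the overlap rule, the higher-scoring 50% of each list (ties broken by position), lists of equal length, the promoter window, the authors' promoter class, rotation within promoter and other peaks, the assignment of peaks and the background. Those chosen after seeing the data left out the recurrent scores, repeats or the sex chromosomes, split promoter from other peaks, or changed assignment and background together. Recurrent scores were values held by at least 100 Foxp4 peaks and by more than 3 times as many as either neighbouring value.

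The statistics were tested on simulated data. Unrelated lists gave an overlap of 0.917-fold the rotated mean, and with 2000 overlapping peaks planted 2110 overlaps were found. In 100 simulated draws with no list raised, 0 of 2300 tests of other lists were called. Computation used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.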

Results

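Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map the forkhead transcription factor Foxp4 and the histone mark H3K27ac, acetylation of histone H3 at lysine 27 that marks active promoters and enhancers, in mouse beige adipocytes. Beige adipocytes are thermogenic fat cells that arise within white fat. Here they were differentiated in culture from stromal-vascular cells of the inguinal white fat pad of C57BL/6 mice. The 3 libraries were an input DNA library, a Foxp4 ChIP library and an H3K27ac ChIP library. Peak lists of both ChIP libraries were analysed, with 1 library each and no replicate, and the input was not used here. Every p-value therefore describes the 2 lists and their annotation, not the variation between cultures. Sequencing depth is unknown from the peak lists, and intervals are exact (Clopper-Pearson) 95% intervals that cover counting error only. Each peak carries the authors' score, which was used only to rank and describe peaks within its own list.

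The Foxp4 list held 16937 peaks on chromosomes 1 to 19, X and Y, with a median width of 354 bp and a median score of 27. The H3K27ac list held 17564 peaks with a median width of 529 bp and a median score of 40. The Foxp4 peaks covered 6.72 Mb of the mm10 assembly and the H3K27ac peaks 12.2 Mb.

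To compare where both lists lay in the genome, peaks were grouped by distance to a transcription start site (TSS) and by annotation class. Foxp4 peaks lay mostly away from promoters. Of the Foxp4 peaks, 1605 (9.48%, interval 9.04 to 9.93%) had their centre within 1000 bp of a TSS, against 6415 H3K27ac peaks (36.5%, interval 35.8 to 37.2%). The difference, Foxp4 minus H3K27ac, was -27.0 percentage points, and the p of the two-sided Fisher's exact test was too small for the software to represent. By the authors' narrower promoter class the difference was -10.8 points, and without the Foxp4 peaks at the recurrent scores described further on it was -16.8 points. Intergenic sequence held 45.2% of Foxp4 peaks and 27.2% of H3K27ac peaks (adjusted p = 5.1e-266 by Fisher's exact test), and introns held 43.5% and 45.8% (adjusted p = 1.5e-05 by the same exact test). Peaks in the 5' UTR made up 0.425% of the Foxp4 list and 2.53% of the H3K27ac list. CpG islands, the GC-rich stretches found at many promoters, were the detailed annotation of 153 Foxp4 peaks (0.903%) and 1312 H3K27ac peaks (7.47%). Nearly all peaks of the promoter, exon and UTR classes kept their class in the detailed annotation. CpG islands at those peaks are therefore mostly left out of these counts, which are not the full share of peaks in CpG islands. Relative to the genome, both lists were enriched at promoters: the authors' deposited table gave a log2 ratio of observed to expected promoter peaks of 2.48 for Foxp4 and 3.95 for H3K27ac. In intergenic sequence both lists held fewer peaks than expected, with log2 ratios of -0.434 and -1.166. For introns the ratios were 0.328 and 0.405.

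**Figure D1:**
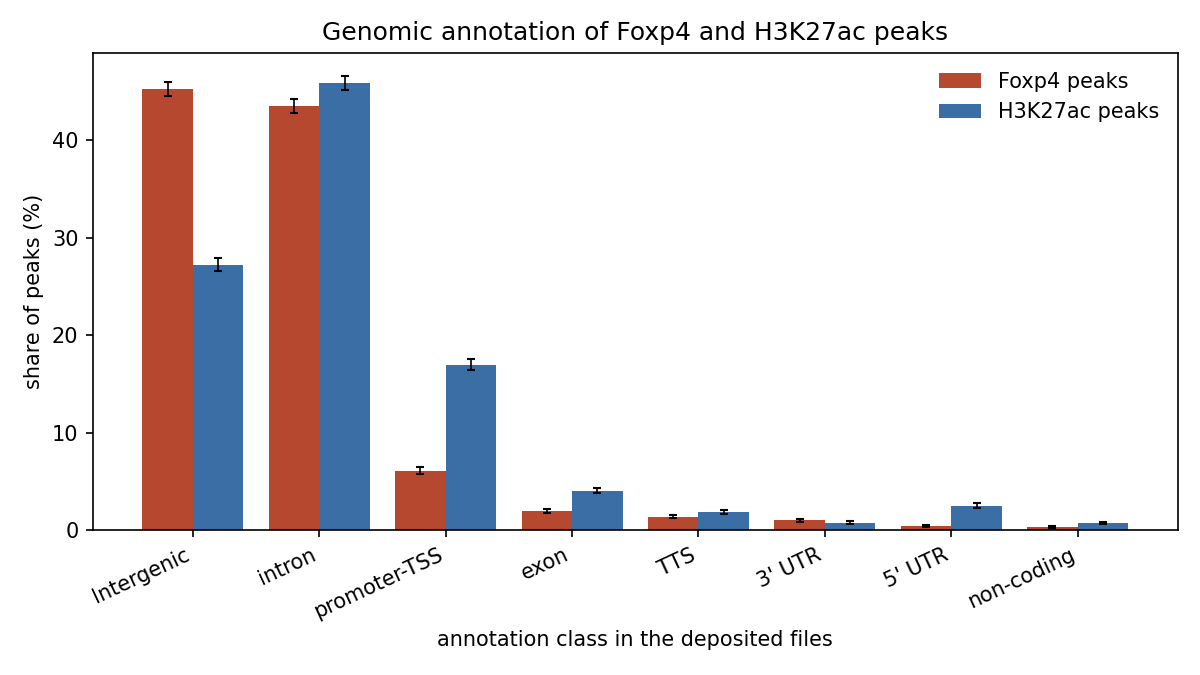
Share of peaks (%, vertical axis) in each annotation class of the deposited files for the Foxp4 and H3K27ac lists, 1 library each; error bars are exact 95% intervals. Intergenic sequence held 45.2% of Foxp4 peaks and 27.2% of H3K27ac peaks, and the promoter class, narrower than the 1000 bp window, held 6.12% and 16.9%.

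Foxp4 peaks and acetylated regions overlapped more often than after rotation of the peaks along the chromosomes. In all, 1391 Foxp4 peaks (8.21%, interval 7.80 to 8.64%) shared at least 1 bp with an H3K27ac peak. When the Foxp4 peaks were rotated along each chromosome 1000 times, 0.801% overlapped on average and 1.02% at most, so the observed share was 10.3-fold the rotated mean (two-sided permutation p = 0.001, the smallest that the rotations can give). In the other direction, 1390 H3K27ac peaks (7.91%, interval 7.52 to 8.32%) overlapped a Foxp4 peak, against 0.773% after rotation (permutation p = 0.001). This share was 2.52% where at least 50% of the H3K27ac peak had to be covered, 3.35% where its centre had to lie inside a Foxp4 peak and 5.01% without the recurrent Foxp4 scores. Promoter peaks overlapped more often than the rest: 679 of 1605 Foxp4 promoter peaks (42.3%, interval 39.9 to 44.8%) overlapped H3K27ac, against 712 of 15332 peaks elsewhere (4.64%, interval 4.32 to 4.99%). The latter share was still 5.85-fold its rotated mean of 0.793%. Intron and intergenic Foxp4 peaks overlapped H3K27ac in 7.03% and 4.15% of cases.

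The overlap share depended on which Foxp4 peaks were counted. A set of 6 score values (21, 27, 34, 41, 49 and 57) held 12388 Foxp4 peaks, 73.1% of the list. These recurrent scores were noticed after the data were examined. Peaks at these scores overlapped H3K27ac in 4.17% of cases, and the other 4549 peaks in 19.2% (interval 18.1 to 20.4%), which was 5.28-fold and 23.1-fold the rotated mean. In the higher-scoring 50% of each list the share was 8.36%, 17.9-fold its rotated mean.

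**Figure D2:**
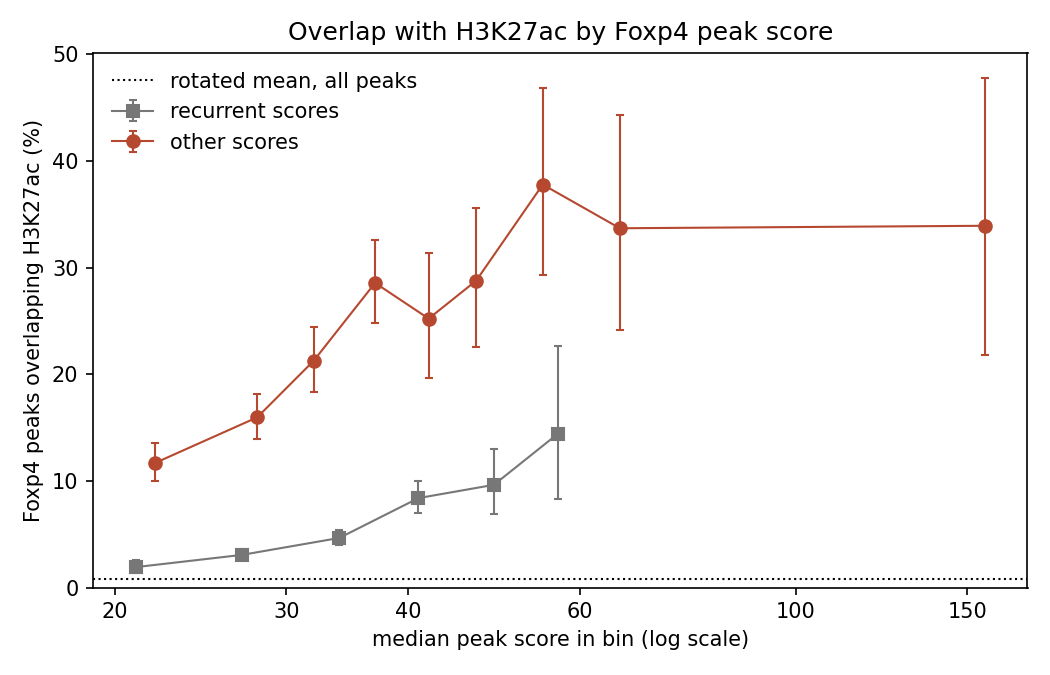
Share of Foxp4 peaks that overlapped an H3K27ac peak (%, vertical axis) by the median score of each score bin (horizontal log axis), for peaks at the 6 recurrent scores and for peaks at other scores; bars are exact 95% intervals and the dotted line is the mean over rotations of the whole list, 0.801%. The share rose from 1.92% at a score of 21 to 14.4% at 57 among the recurrent scores, and stood at 11.7% in the lowest bin of the other scores.

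Foxp4 peaks inside acetylated regions scored higher than those outside. The median score was 33 inside (quartiles 27 and 41, 1391 peaks) and 27 outside (quartiles 26 and 34, 15546 peaks), a difference of 6 (permutation test with 100000 resamples, two-sided p = 1e-05, the smallest it can give). Among promoter peaks alone the medians were 33 and 30 (permutation p = 0.00334), and among peaks outside promoters they were 33 and 27 (permutation p = 1e-05). H3K27ac peaks that carried a Foxp4 peak likewise had a higher median score within their own list, 51 against 39 (permutation p = 1e-05). Peak width was not matched in this test, and a wider H3K27ac peak can meet a Foxp4 peak more easily by its length alone.

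At the level of genes, 1424 of 21031 protein-coding genes had a Foxp4 promoter peak, 5470 had an H3K27ac promoter peak and 779 had both. A Foxp4 promoter peak was present at 14.2% of genes with an acetylated promoter and at 4.15% of the others (odds ratio 3.84, 95% interval 3.44 to 4.28, two-sided Fisher's exact test p = 5.0e-126). Conversely, 54.7% of the genes with a Foxp4 promoter peak also had an H3K27ac promoter peak. Peaks were matched here by gene and not by position, so both could lie at different starts of a gene, as at Pparg. A gene whose H3K27ac peak had its centre more than 1000 bp from the TSS, as at Cebpb, counted among the others.

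The highest-scoring Foxp4 promoter peaks that overlapped H3K27ac were led by Gt(ROSA)26Sor, the locus widely used for transgene insertion, with a score of 292 at chromosome 6, 113075797 to 113077081, in intron 1, inside an H3K27ac peak of score 96. Klhl24, encoding a kelch-like protein, followed with 113 in a CpG island of its intron 1 (chromosome 16, 20097732 to 20098303). Ubald1 had a score of 108 at its promoter (chromosome 16, 4880236 to 4880790), and the pseudogene Pisd-ps1 one of 95. Ncoa1, a coactivator of nuclear receptors, scored 92 at its promoter (chromosome 12, 4477621 to 4478477). Trib1, a pseudokinase, scored 76 (chromosome 15, 59648297 to 59648881), and Nckap1, a component of the WAVE actin regulatory complex, scored 74. Stat6, the transcription factor of interleukin-4 signalling, and the prostaglandin synthase gene Ptges2 both scored 71, and the kinase gene Rps6ka5 scored 69. Foxp4 promoter peaks without H3K27ac overlap were led by Pgk1, a glycolytic enzyme gene on chromosome X (106186708 to 106187239), with a score of 144. Psen2, a presenilin gene, followed with 91, the Wnt receptor gene Fzd6 with 74, the transcription factor gene Etv5 with 71 and the huntingtin gene Htt with 70. An H3K27ac peak lay close to, but outside, the Foxp4 peak at Pgk1, Psen2 and Fzd6, with H3K27ac scores of 23, 43 and 21.

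Of 20 adipocyte and forkhead genes chosen before the data were examined, 14 had at least 1 Foxp4 peak assigned, 14 had an H3K27ac peak and 8 had a Foxp4 peak that overlapped H3K27ac. Pparg, Cebpb and Cebpa each carried a Foxp4 peak near a TSS. At Pparg, the master regulator of fat cell differentiation, a Foxp4 peak with a score of 55 lay 128 bp upstream of the downstream transcript start (chromosome 6, 115421746 to 115422131). It overlapped no H3K27ac peak, and both H3K27ac promoter peaks of Pparg lay at upstream starts, between 115360786 and 115362066. At Cebpb, an early adipogenic factor, a Foxp4 peak of score 47 lay 687 bp upstream of the TSS (chromosome 2, 167688016 to 167688441), inside an H3K27ac peak of score 108. At Cebpa, which acts with Pparg, a Foxp4 peak of score 29 spanned the TSS, with its centre in the single exon (chromosome 7, 35119058 to 35119974). It overlapped an H3K27ac peak of score 74.

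Of the lipid storage genes, Lipe, Plin1 and Fabp4 had a Foxp4 peak that overlapped H3K27ac. Lipe, encoding hormone-sensitive lipase, had a Foxp4 promoter peak of score 41 (chromosome 7, 25389985 to 25390591) overlapping an H3K27ac peak of score 58. Plin1, the perilipin of the lipid droplet surface, had a Foxp4 peak of score 34 in intron 2, 917 bp downstream of the TSS, that overlapped H3K27ac. A second one of score 55 in intron 3 did not overlap (chromosome 7, 79729260 to 79730117). At Fabp4, a fatty acid binding protein gene, the Foxp4 peak of score 46 lay 3445 bp upstream (chromosome 3, 10211595 to 10212528) and overlapped H3K27ac. Adipoq, encoding the hormone adiponectin, had a Foxp4 peak of score 34 in intron 1 (chromosome 16, 23148505 to 23149598) and no H3K27ac peak.

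Ucp1, the uncoupling protein of brown and beige fat, Prdm16, Dio2 and Adrb3 had no peak in either list. Ppargc1a, a coactivator of mitochondrial biogenesis, had 5 Foxp4 peaks, of which 1 of score 34 lay at the promoter (chromosome 5, 51553815 to 51554135), and none overlapped H3K27ac. Cidea had 1 Foxp4 peak of score 21, 24184 bp upstream of its TSS, Elovl3 had 1 of score 40 at 4155 bp downstream of its TSS, and neither overlapped H3K27ac. Cox8b had a single H3K27ac peak and no Foxp4 peak. Ebf2, a factor of brown and beige fat identity, had 2 Foxp4 peaks in intron 5, both of score 21, and 6 H3K27ac peaks. Pdgfra, a marker of adipocyte progenitors, had 1 Foxp4 peak of score 32 in intron 1 (chromosome 5, 75154522 to 75154820) within an H3K27ac peak of score 64. Among forkhead genes, Foxo1 had 4 Foxp4 peaks, 2 of them overlapping its single H3K27ac peak of score 109. Foxp1 had 11 Foxp4 and 12 H3K27ac peaks with 1 Foxp4 peak overlapping. Foxp4 itself had 3 H3K27ac peaks and no Foxp4 peak. The Foxp4 peaks of scores 21, 27, 34 and 41 at these fixed genes, including peaks of score 27 at Ppargc1a and Foxp1, stood at recurrent scores. Absence from a list means that no peak was called in these libraries, whose depth is unknown.

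**Figure D3:**
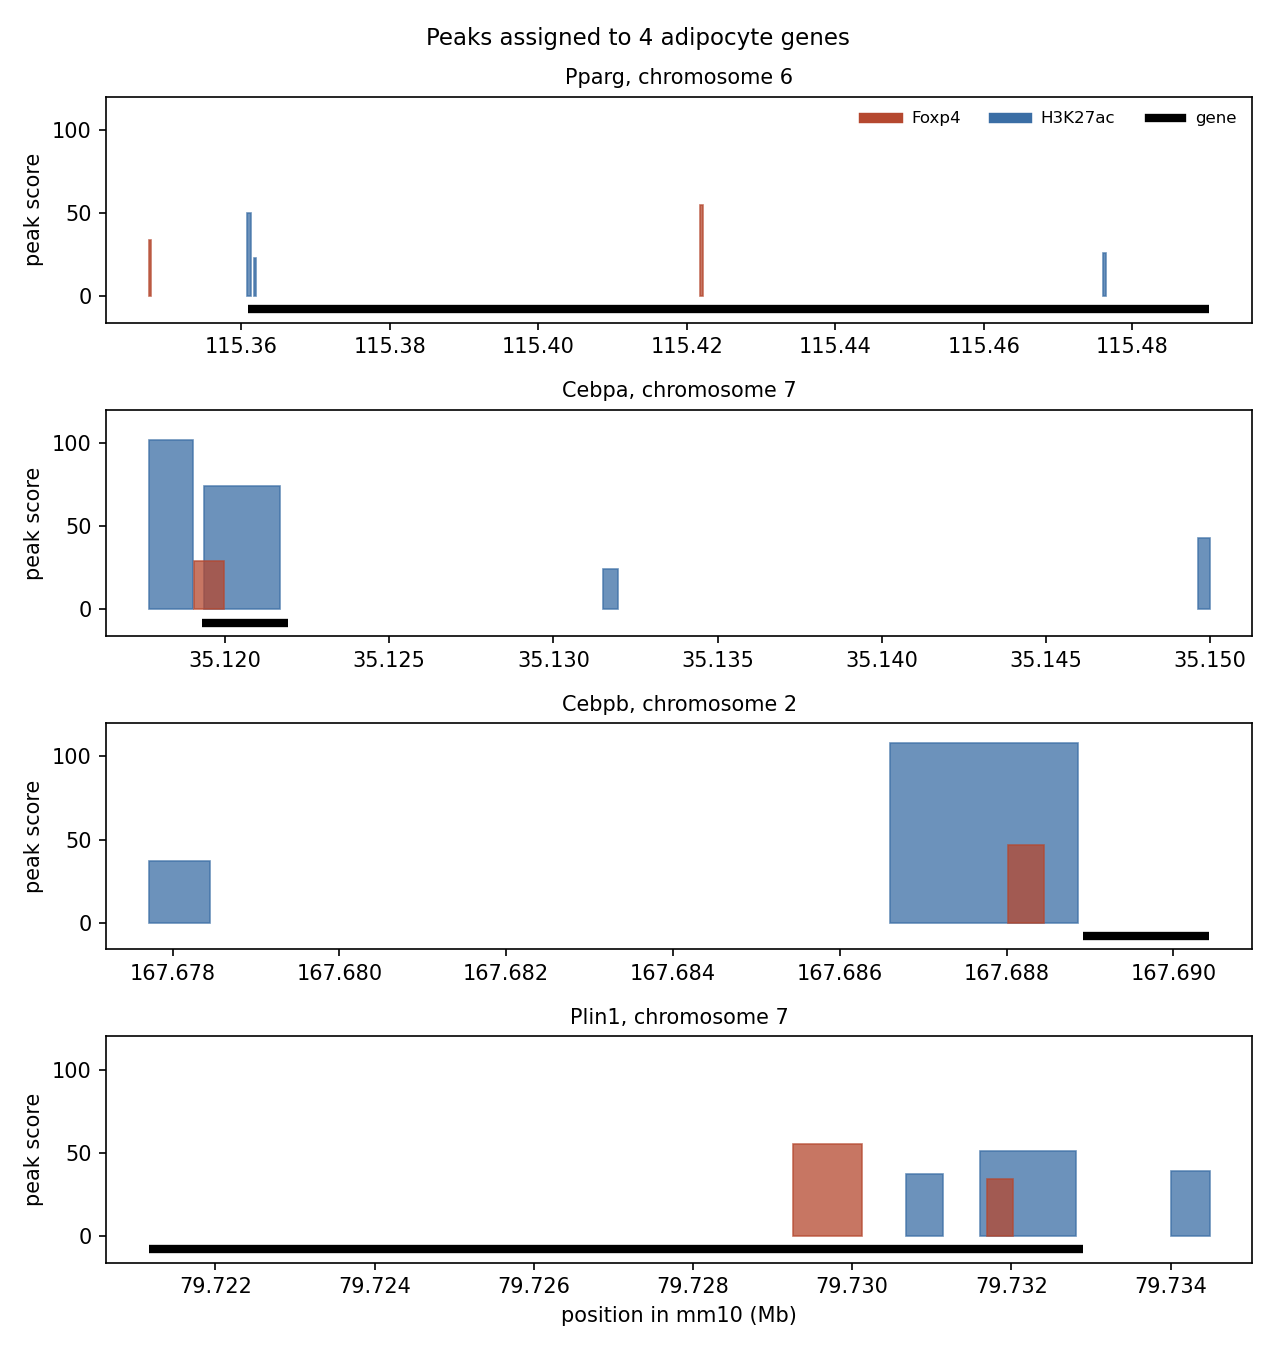
Peaks assigned to Pparg, Cebpa, Cebpb and Plin1, drawn to scale along mm10 (horizontal axis, Mb) as boxes whose height is the authors' score, with the gene as a black bar; scores are not comparable between the Foxp4 and H3K27ac lists. The Foxp4 peak of score 55 at Pparg stands apart from the H3K27ac peaks, whereas the Foxp4 peak of score 47 at Cebpb lies inside an H3K27ac peak.

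To ask which gene groups were acetylated in these cells, H3K27ac promoter peaks were counted in 25 gene lists fixed before the data were examined. Over all protein-coding genes 26.01% had an H3K27ac promoter peak. The share was higher in 14 lists and lower in 2 (two-sided Fisher's exact test, Benjamini-Hochberg over the lists). Among lists of mitochondrial metabolism, the mark was present at 36 of 54 oxidative phosphorylation genes (66.7%, adjusted exact p = 1.1e-08), 17 of 22 tricarboxylic acid cycle genes (77.3%, adjusted exact p = 3.6e-06) and 14 of 24 fatty acid oxidation genes (58.3%, adjusted exact p = 0.0018). Glycolysis genes had 13 of 20 (adjusted exact p = 0.00078). Of the adipocyte lists, 14 of 23 adipogenic transcription factors (60.9%, adjusted exact p = 0.0011), 16 of 30 lipid droplet and adipocyte genes (53.3%, adjusted exact p = 0.0027) and 10 of 20 lipogenesis genes (50.0%, adjusted exact p = 0.035) carried the mark. Signalling and stress lists were also higher, with 18 of 22 unfolded protein and heat shock response genes (81.8%, adjusted exact p = 8.6e-07), 15 of 19 circadian clock genes (78.9%, adjusted exact p = 8.8e-06), 17 of 22 insulin signalling genes (77.3%, adjusted exact p = 3.6e-06), 19 of 26 TGF beta and BMP signalling genes (73.1%, adjusted exact p = 3.6e-06) and 12 of 20 beta adrenergic and cAMP genes (adjusted exact p = 0.0027). Extracellular matrix genes had 16 of 25 (adjusted exact p = 0.00026) and cytosolic ribosomal protein genes 22 of 40 (adjusted exact p = 0.00030).

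The thermogenic and beige fat list had 5 of 24 members with an H3K27ac promoter peak (20.8%, adjusted exact p = 0.75). These were Ebf2, Letmd1, Pdk4, Ppargc1b and Zfp516. Skeletal muscle markers had 0 of 20 (0%, upper bound 16.8%, adjusted exact p = 0.0067) and hepatocyte markers 1 of 22, Apoa2 (4.55%, adjusted exact p = 0.039), both lower than other genes. In the higher-scoring 50% of the H3K27ac list, 0 lists were lower by this test. Neuronal markers had 1 of 20 (adjusted exact p = 0.055), endothelial markers 1 of 18 (adjusted exact p = 0.079), macrophage markers 3 of 22 (adjusted exact p = 0.29) and smooth muscle and mural cell markers 3 of 16 (adjusted exact p = 0.84). The shares among preadipocyte and stromal progenitor genes (6 of 21, adjusted exact p = 0.84), Wnt signalling genes (11 of 27, adjusted exact p = 0.16), forkhead family genes (8 of 27, adjusted exact p = 0.75) and cell cycle genes (7 of 26, adjusted exact p = 1) did not pass the test.

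To ask whether Foxp4 favoured particular groups among acetylated promoters, the lists were then tested within the 5470 genes with an H3K27ac promoter peak, of which 14.2% had a Foxp4 promoter peak. None of the 24 lists with a member among them passed Fisher's exact test after adjustment, and 1 had an unadjusted p under 0.05. That list was insulin signalling, with 6 of 17 genes (35.3%, interval 14.2 to 61.7%, adjusted exact p = 0.60). In the higher-scoring 50% of each list the difference of this list from other acetylated promoters was -4.03 points, against 21.1 points in the full lists. Its members with the highest-scoring Foxp4 promoter peaks were Socs3 (32), Rptor (27) and Pik3r1 (26). Circadian clock genes had 5 of 15 (33.3%, adjusted exact p = 0.61), with Arntl, encoding the core clock factor BMAL1, at a score of 49, Tef at 39 and Nfil3 at 38. The scores of Rptor and Arntl are recurrent ones. Adipogenic transcription factors had 4 of 14 (28.6%, adjusted exact p = 0.92), and the thermogenic list had 0 of 5. The 4 adipogenic factors include Pparg, whose Foxp4 promoter peak lay at another start than its H3K27ac promoter peaks. Cebpb was not among the 14, since the H3K27ac peak around its Foxp4 peak had its centre 1188 bp upstream of the TSS. With the TSS window widened to 3000 bp, circadian clock genes (10 of 16, adjusted exact p = 0.0055) and adipogenic transcription factors (9 of 18, adjusted exact p = 0.048) passed. Over all 7 alternatives the adjusted exact p ranged from 0.0055 to 1 for the circadian list and from 0.00010 to 0.79 for the adipogenic list. In simulated data, a list of 17 members raised by 20 percentage points was called in 20% of draws and one raised by 40 points in 74%.

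Against all protein-coding genes, of which 6.77% had a Foxp4 promoter peak, 2 lists passed Fisher's exact test. Adipogenic transcription factors had 8 of 23 members (34.8%, interval 16.4 to 57.3%, adjusted exact p = 0.0021), led by Pparg (55), Cebpb (47), the carbohydrate response factor Mlxipl (40) and the lipogenic factor Srebf1 (35). Insulin signalling genes had 6 of 22 (27.3%, adjusted exact p = 0.035). Lipogenesis genes had 5 of 20 (adjusted exact p = 0.058), with the desaturase genes Scd1 (57) and Fads2 (47) highest. Circadian clock genes had 5 of 19 (adjusted exact p = 0.058), and lipid droplet and adipocyte genes 5 of 30 (adjusted exact p = 0.24), including Lipe and Mgll, both lipases, at 41. The scores of Scd1, Lipe and Mgll are recurrent ones. Oxidative phosphorylation genes had 5 of 54 (adjusted exact p = 0.89) and the thermogenic list 1 of 24, Ppargc1a (adjusted exact p = 1). Of the markers of other cell types, smooth muscle and mural cell markers had 3 of 16 (18.8%, adjusted exact p = 0.37), macrophage markers 1 of 22 and skeletal muscle markers 1 of 20. Hepatocyte, neuronal and endothelial markers had 0 of 22, 0 of 20 and 0 of 18, with upper bounds of 15.4%, 16.8% and 18.5%, and none of these 6 lists passed the test.

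**Figure D4:**
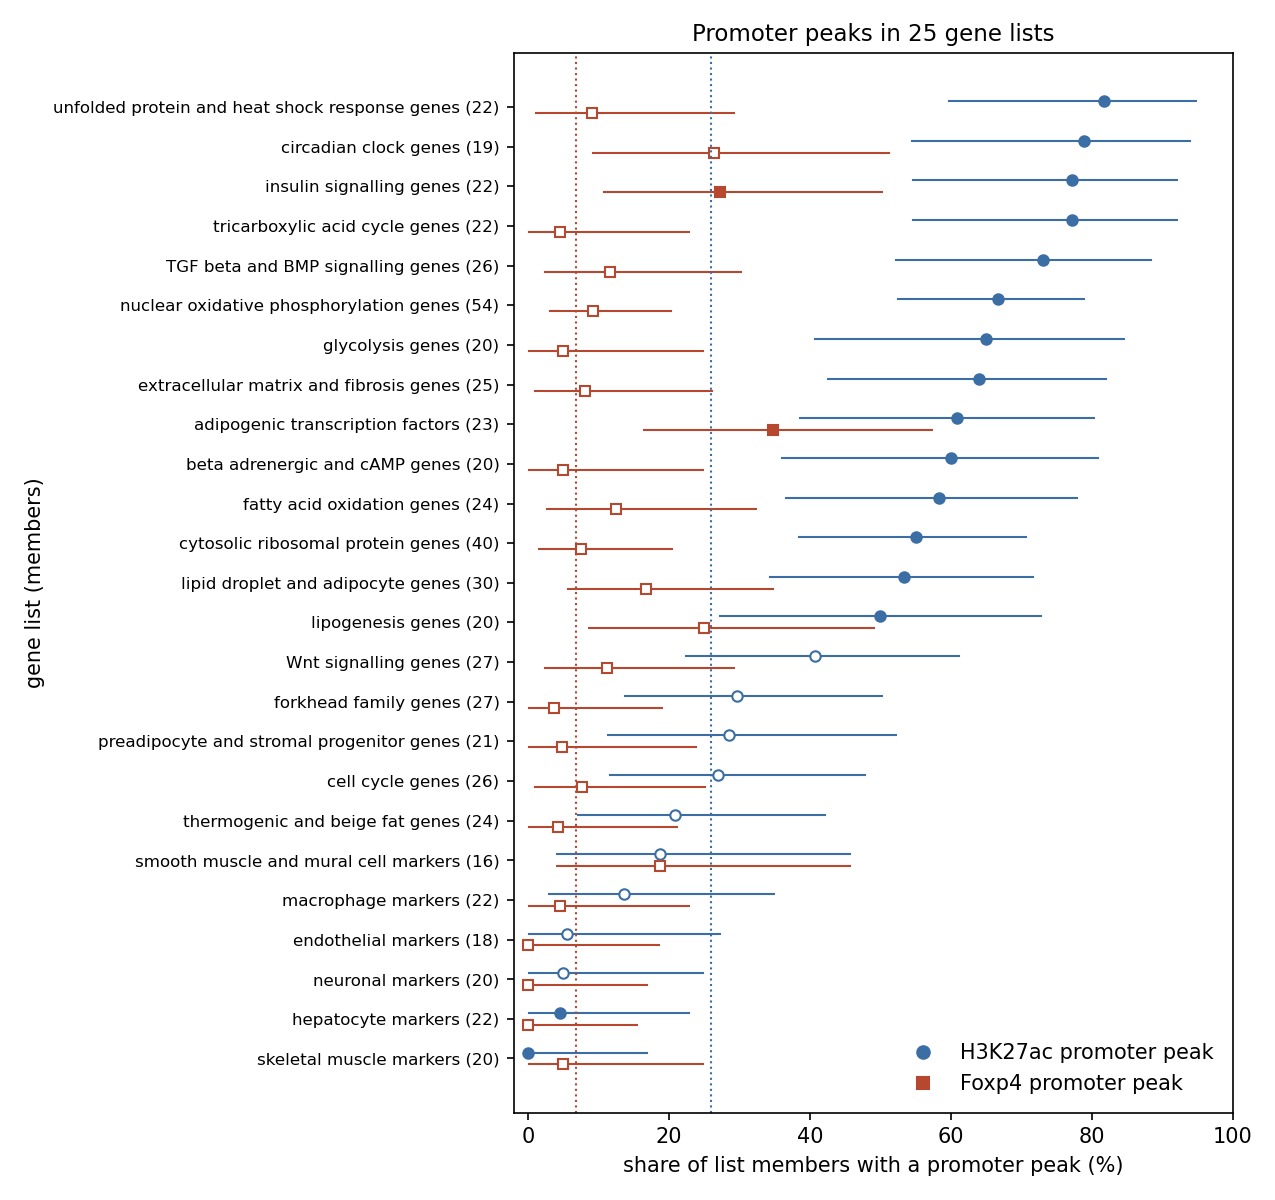
Share of the members of each of 25 gene lists (vertical axis, number of members in brackets) with an H3K27ac or a Foxp4 promoter peak (%, horizontal axis); lines are exact 95% intervals, filled symbols have an adjusted p under 0.05 by Fisher's exact test over all protein-coding genes, and dotted lines are the shares over all genes, 26.01% and 6.77%. For Foxp4 the filled symbols are adipogenic transcription factors at 34.8% and insulin signalling genes at 27.3%.

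Of the 5 highest-scoring Foxp4 peaks, 4 were annotated to repeats. The highest score, 1357, belonged to an intergenic (CCTAA)n simple repeat on chromosome 18 (83543568 to 83544153). The next, 418, lay in the 3' UTR of Lars2, encoding a mitochondrial leucyl-tRNA synthetase, on chromosome 9 (123461862 to 123462168). Since peaks of the UTR class mostly keep that class in the detailed annotation, whether this peak lies in a repeat cannot be told from it. The following 3 lay in intergenic major satellite repeats (GSAT_MM): chromosome 9, 3010814 to 3011137, with 372, chromosome 14, 19416891 to 19418283, with 317, and chromosome 9, 3023424 to 3024598, with 308. The peaks of scores 317 and 308 overlapped H3K27ac, and the other 3 of these 5 did not. The genes assigned the most Foxp4 peaks were Cdh20, Flrt3 and Lrrc4c with 14 each, followed by Acvr2a, Brinp3 and Utrn with 13 each. These counts go by the nearest TSS and do not allow for the length of genome nearest to each gene. Of the peaks at these 6 genes, 1, at Utrn, overlapped H3K27ac. Recurrent scores were held by 13 of the peaks at Cdh20, 12 at Flrt3 and 11 at Lrrc4c.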

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

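The tests of explanations in this part were all chosen after the results were seen. The design holds no second condition, and apart from binding of Foxp4 to satellites no biological explanation was tested. A signal outside the main measurement was 1 Foxp4 peak on the mitochondrial genome (15647 to 16017) with a score of 56, where the H3K27ac list had 0 peaks. It was left out of the comparisons of the report.

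Satellite and simple repeats were frequent among the strongest Foxp4 peaks. Of the strongest 100, 29 lay in satellites, 24 of them on chromosome 9, and 4 in telomere-like simple repeats, whereas satellites made up 0.143% of the remaining peaks. A candidate explanation is that reads from many repeat copies were placed on the few copies in the assembly. It would give peaks at the same places whatever the antibody, but the 15.1% of satellite Foxp4 peaks that overlapped an H3K27ac peak (8 of 53, interval 6.75 to 27.6%, which treats clustered peaks as independent) was not set apart from the 8.21% of the whole list. With 0 satellites among the strongest 100 H3K27ac peaks, this explanation and binding of Foxp4 to these repeats cannot be told apart, since the input was not used here.

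Foxp4 peaks at the 6 recurrent scores overlapped H3K27ac in 4.17% of cases and the others in 19.2%. Pile-ups with no link to chromatin state are argued against as the whole cause, since 4.17% (interval 3.82 to 4.53%) exceeds the highest rotation, 1.12%. A smaller promoter share at the recurrent scores (5.70% against 19.8%) is also argued against as the whole cause: outside promoters the overlap was 2.41% against 11.8% (odds ratio 0.184, Fisher's exact test p = 3.1e-102). Recurrent values may arise where few reads meet a uniform background, and the others where input reads raise a local background over open chromatin; this cannot be told apart from a difference in binding without input coverage.

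The high Foxp4 scores at Gt(ROSA)26Sor (292) and Pgk1 (144) concern sequences common in mouse targeting constructs and expression vectors. Strong acetylation of an open promoter would give a high H3K27ac score, but that at Pgk1, 23, lay under the median of H3K27ac promoter peaks, 51. Pgk1 lies on chromosome X, which held 12.0 H3K27ac peaks per 100 genes against 87.0 on the autosomes, with median scores of 39 and 40. Whether X was filtered is not known, so this single score does not decide the question. At Gt(ROSA)26Sor the H3K27ac score was 96, reached by 10.3% of H3K27ac promoter peaks, so strong acetylation stays open there too. Construct DNA could give both peaks, which the scores of 292 and 144, for which the loci were picked, do not decide. It cannot be told apart from binding of Foxp4, because read sequences and the input were not used here and the labels mention no construct.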

How the results depend on the processing

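The 3 libraries give no replicate to leave out, and unknown depth limits every absence of a peak. No paired analysis was possible because each antibody had 1 library. The forkhead motif alternatives and the one ranking peaks by −log10 q were not run, for want of a genome sequence and of a q-value column. Settings without recurrent scores, without repeats, without chromosomes X and Y, within or outside promoters, and with assignment and background changed together were chosen after seeing the data. Of 81 alternative values, 67 were counted as keeping direction and side of the threshold, 8 passed it where the original had not, 4 counts of lists moved and 2 turned direction. The 67 include small changes in the number of H3K27ac lists, from 14 to 13 and from 2 to 3. All 9 alternatives for Foxp4 peaks overlapping H3K27ac stayed above rotation, from 5.79% with at least 50% of the peak covered to 19.2% without the recurrent scores. All 4 for the reverse overlap did as well, from 2.52% to 8.08%. Among the 9, the rotation within promoter and other peaks also moved promoter peaks away from promoters. It therefore does not test whether the overlap exceeds that of a shared promoter location. Direction and side of the threshold were also kept by the 6 for the promoter share difference (-37.6 to -10.8 points), the 5 for the score difference (3 to 6) and the 4 for genes with both peaks (odds ratio 3.43 to 4.97).

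Lists with a Foxp4 promoter peak depended on the setting. Among acetylated promoters 0 lists passed, against 2 with the 3000 bp window, 2 with all genes as background, 0 with any assigned peak and 8 with any assigned peak over all genes, where both choices changed. The cause was not tested. The insulin signalling difference turned from 21.1 to -4.03 points in the higher-scoring 50% of each list. That of lipid droplet and adipocyte genes turned from 10.8 to -2.95 points without the recurrent scores. Neither list passed the test in the setting where it turned, and the cause was not tested. For H3K27ac, lists higher than other genes numbered 14, against 13 in the higher-scoring 50% of the list and 14 with the 3000 bp window. Lipogenesis genes were the list that no longer passed in the higher-scoring 50%. Lists lower than other genes numbered 2, against 0 in the higher-scoring 50% of the list, where fewer genes carry the mark, and 3 with the 3000 bp window.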

Other observations

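Tests in this part were chosen after the results were seen, except the test of peaks near H3K27ac and that of any Foxp4 peak among acetylated promoters, and so were the genes named here. Counting any Foxp4 peak assigned to a gene, 36.6% of protein-coding genes had one, and 8 lists were higher by Fisher's exact test. Adipogenic transcription factors had 19 of 23 (82.6%, adjusted exact p = 0.00010), including Klf4 with 10 peaks and Rxra, Nr3c1 and Zfp423 with 7 each. TGF beta and BMP signalling genes had 21 of 26 (80.8%, adjusted exact p = 0.00010), including the activin receptor gene Acvr2a with 13. Insulin signalling genes had 17 of 22 (adjusted exact p = 0.0014) and extracellular matrix genes 18 of 25 (adjusted exact p = 0.0032). Lipid droplet and adipocyte genes (18 of 30), lipogenesis genes (13 of 20), Wnt signalling genes (17 of 27) and endothelial markers (12 of 18) each had an adjusted exact p of 0.039. Thermogenic and beige fat genes had 7 of 24 (adjusted exact p = 0.78). Among genes with an H3K27ac promoter peak, of which 50.8% had a Foxp4 peak assigned, 0 of 24 lists passed Fisher's exact test and 5 had an unadjusted p under 0.05. Of these 5, TGF beta and BMP genes (15 of 19), extracellular matrix genes (13 of 16) and insulin signalling genes (13 of 17) had a larger share than the other genes, and tricarboxylic acid cycle genes (4 of 17) and fatty acid oxidation genes (3 of 14) a smaller one, with adjusted exact p of 0.19 to 0.20. The adipogenic factors, not among the 5, had 11 of 14 (adjusted exact p = 0.20). Counting any H3K27ac peak in the same way over all genes, 15 lists were higher, with 20 of 23 adipogenic factors (adjusted exact p = 7.1e-06).

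A gene with a long stretch of genome nearest to it could gather peaks by its length. The median stretch was 135 kb for the adipogenic factors and 184 kb for the TGF beta and BMP genes, against 45.9 kb for all genes. Among 10000 random lists matched on this length, the central 95% had a Foxp4 peak at 30.4 to 69.6% of members for the adipogenic factors and at 34.6 to 69.2% for the TGF beta and BMP genes. The observed 82.6% and 80.8% lay above, at percentiles 99.97 and 99.88, which argues against length as the whole cause. Of the 25 lists, 9 had a percentile above 97.5 among their matched lists and 0 one below 2.5. Of the 9, glycolysis genes, endothelial markers and circadian clock genes (percentiles 98.4, 98.2 and 98.0) stood at the upper bound of the central 95% and not above it, and Wnt signalling genes lay at 93.0. The stretches were measured between protein-coding genes only.

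Foxp4 peaks without H3K27ac overlap were tested for lying near acetylated regions. Within 1000 bp of an H3K27ac peak lay 5.13% of them (797 of 15546, interval 4.79 to 5.49%), 4.04-fold the rotated 1.27% and above the highest of 200 rotations, 1.56%. Within 5000 bp lay 13.2% (2054 peaks) against 5.53% after rotation, so the excess was not confined to the nearest 1000 bp. Acetylated regions called too narrowly to reach some Foxp4 peaks could give part of the 5.13%. Whether they also bear on the excess farther away cannot be told from the peak lists, and the cause of that excess was not tested.

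LINE elements held 1984 Foxp4 peaks (11.7%) and 561 H3K27ac peaks (3.19%; odds ratio 4.02, Fisher's exact test adjusted p = 8.5e-211), and LTR elements 1623 and 691. Young L1 families held 661 Foxp4 and 125 H3K27ac peaks, and 3 of the Foxp4 peaks overlapped H3K27ac (0.454%, interval 0.0937 to 1.32%). Of these young L1 peaks, 87.4% had one of the recurrent scores, against 83.8% of the other LINE peaks and 73.1% of the whole Foxp4 list. The other LINE peaks overlapped H3K27ac in 1.06% of cases. The authors' deposited table gave a log2 ratio of observed to expected LINE peaks of -0.77 for Foxp4 and -2.64 for H3K27ac.

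Chromosome X held 68 Foxp4 peaks, or 7.51 per 100 protein-coding genes against 84.1 on the autosomes, where the lowest chromosome had 49.5. For H3K27ac the values were 109 peaks, 12.0 per 100 genes, 87.0 on the autosomes and 58.9 on the lowest autosome. The sources used here do not say whether chromosome X was filtered in processing.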
